A study of Homo sapiens with 4 samples.

How the data were processed

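RNA-seq was carried out on HT1376, an established bladder cancer cell line, in 4 samples of total RNA. Per the labels' protocols, 2 samples were treated with a control labelled WFI and 2 with 1 nM enfortumab vedotin (EV) for 48 h, and a directional library kit was used. EV is an antibody-drug conjugate against nectin-4 whose payload, monomethyl auristatin E, disrupts microtubules. The deposited table holds whole-number counts per gene for each sample, with no normalization by the authors. Per the submitters' processing notes, the genome build was hg38. The aligner, the counting tool, its strand setting and the annotation release are not given in the sources used here.

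The table lists 61860 genes, of which 61757 identifiers matched a symbol and 103 did not. Totals ran from 19368791 to 20727175 counts per sample, and 38205 genes had at least 1 count. The 37 genes of the mitochondrial genome are listed with 0 counts in all 4 samples, so mitochondrial transcripts and their share as a sign of cell state could not be assessed. Genes of the MHC region on chromosome 6 were also near 0: of 153 protein coding genes between 29 and 33 Mb, 2 had 10 or more counts in every sample (1.3%), against 511 of 886 on the rest of the chromosome (57.7%). HLA-C, TAP1, TUBB, HSPA1A and IER3 therefore have no usable measurement here.

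Gene coordinates, spans, spliced lengths and GC content came from GENCODE release 29 on the same build, which holds 17073 of the 17465 genes tested. Spliced length was the merged length of all annotated exons of a gene, which can exceed that of the transcript expressed. Genes that overlap another gene on the same strand, antisense genes, and genes with near-identical copies are uncertain, because the counting could have split or shared their reads.

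Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, filterByExpr on the group, the quasi-likelihood test without robust fitting, and the group as the only term. The filter left 17465 genes. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called changed. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Levels are given as CPM, counts scaled to a common library size with TMM factors, as mean ± SD of 2 samples. Rises and falls are thus relative to the other genes of a sample. For a gene with 0 counts in both controls, the fold is a lower bound against a floor of 3 counts per library, which was 0.144 CPM in the controls. For a gene with 1 to 3 counts in the controls, the ratio is given with its exact binomial 95% interval. Bounds and intervals cover counting error alone. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. Replicates differed by more than counting noise (chi-square per degree of freedom of 2.25 in the controls and 4.72 in EV), so each was counted as a sample. This sets them apart from repeat reads of 1 library, and does not show that they were separate cultures.

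Gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, for lists with at least 5 tested members, adjusted over all lists. Camera with an estimated correlation and fry were run beside it. With 2 samples per group the estimated version rests on few residual degrees of freedom, so a list that it does not call is left undecided. Member counts are given over all genes tested and adjusted over the list alone. The 33 lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule named NECTIN4 and YTHDC1 always. It added the 10 largest rises and the 10 largest falls among changed genes whose groups did not overlap. It took these only from genes that had a symbol or were protein coding, with a mean log2 CPM of 2 or more. It then added the 3 members with the smallest adjusted p in each list that was called or had 3 or more changed members, for 113 genes in total, of which some are not reported here. Further list members are cited as examples or because of a count, and were chosen after their values were seen.

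Alternatives were DESeq2 1.42.0, RLE and upper quartile scaling, no count filter, a filter of 50 or more counts in at least 2 samples, a replicate block, leaving out each sample in turn, and a minimum absolute log2 fold change of 1. A correction for spliced length and GC content was chosen after seeing the data. The procedure was tested on simulated counts drawn from the control means and the real library sizes, with 200 genes changed, equally up and down. Of those that passed the filter, 50% were recovered at an absolute log2 fold change of 0.5, 88% at 1, 95.9% at 2 and 98% at 4 over 15625 genes, and 3.5% of calls were false. In a simulated list test with independent genes the shifted list was called and 0 others. The real contrast changed far more genes and followed spliced length, so these rates need not hold for it.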

Results

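RNA-seq counts were obtained from cells labelled HT1376, a bladder cancer line, after 48 h with the control labelled WFI (n = 2) or with 1 nM enfortumab vedotin (EV, n = 2). Total counts were 19447577 and 19669037 in the controls and 19368791 and 20727175 in EV. At least 1 count was seen for 26258 and 26587 genes in the controls and for 29456 and 28770 genes in EV. The 10 most abundant genes took 4.68% to 5.19% of counts in any library. Across genes, log2 CPM correlated within groups at Pearson r = 0.992 in the controls and 0.982 in EV, and between groups at 0.885 to 0.887. Over both controls the epithelial genes CDH1 and KRT19 had 1 and 7 counts, while the mesenchymal gene VIM stood at 1724 CPM. GRHL2, CLDN3, CLDN7 and ST14 were also near 0 over both controls, with 0, 3, 8 and 7 counts. Of 26 epithelial junction genes listed, 20 passed the filter. Some epithelial genes were high in the same controls, with KRT8 at 733, CLDN1 at 474, KRT18 at 387 and DSG2 at 343 CPM. No other profile of HT1376 was used here, so the identity of the cells was not checked, a limit on what the NECTIN4, luminal, junction and mesenchymal values describe. The series title concerns glucose, lactylation of YTHDC1 and the sensitivity of bladder cancer to EV. The labels give a single contrast, EV against control, so the question addressed is which transcripts differed after EV.

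In EV-treated cells 17 of 24 immediate early genes, 13 of 13 heat shock genes and 48 of 50 ribosomal protein genes tested rose, while 22 of 28 inflammatory and 27 of 40 interferon-response genes fell. Each of these lists was called by camera with a preset correlation, and 0 of the 11 lists so called were called with an estimated correlation (smallest adjusted p = 0.40). With 2 samples per group that version has little power, so it does not decide for or against a list. The interferon and inflammatory lists, with estimated correlations of -0.015 and -0.037, below the preset 0.01, also went to an adjusted p of 0.40. The estimates were far above the preset for the ribosomal protein (0.408), immediate early (0.26) and heat shock (0.165) lists. The camera p-values of those lists thus depend on the preset. FOS, a subunit of the AP-1 transcription factor, rose from 3.99 ± 0.240 to 1002 ± 26.3 CPM (SD, n = 2). BCL2L11, which encodes the pro-apoptotic protein BIM, rose from 9.70 ± 1.01 to 443 ± 16.4 CPM. IL1B, a proinflammatory cytokine, fell from 1702 ± 8.60 to 395 ± 10.6 CPM. In edgeR's quasi-likelihood test 11528 of 17465 genes changed (66%), 6019 higher and 5509 lower in EV. A log2 fold change of at least 1 in size was reached by 5385 of them (3063 higher, 2322 lower), and one of at least 3 by 1562 (1311 higher, 251 lower). The contrast also followed spliced length, the merged length of the exons of a gene. Among 9708 expressed protein coding genes the fold change correlated with spliced length at Spearman rho = -0.427 across genes, which are not independent replicates. The decile of shortest spliced length had a median log2 fold change of 0.51 and the decile of longest spliced length one of -0.74.

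**Figure D1:**
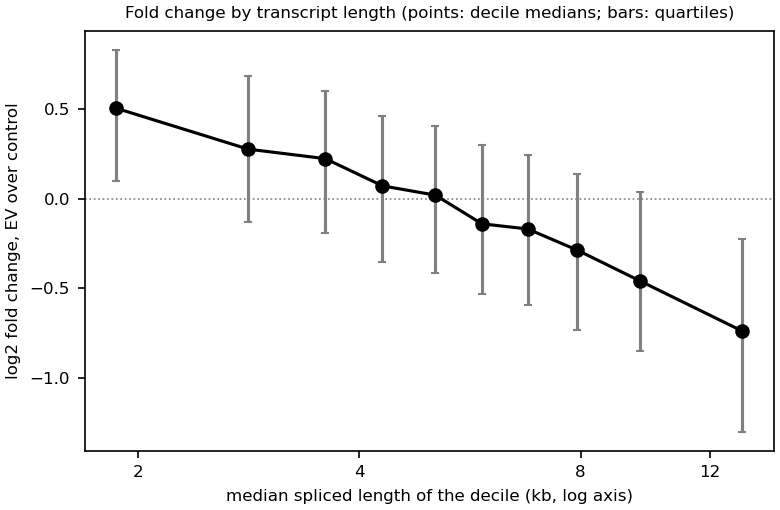
Log2 fold change of EV over control (vertical axis) by median spliced length in kb (log axis) for deciles of 9708 expressed protein coding genes; points are medians and bars quartiles. Medians run from 0.51 in the decile of shortest spliced length to -0.74 in that of the longest.

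NECTIN4, the antigen bound by EV (ENSG00000143217, hg38 chromosome 1, 161070995 to 161089599, minus strand), had few counts, with 28 and 29 in the controls and 9 and 6 in EV. Its level fell from 1.37 ± 0.0216 to 0.402 ± 0.131 CPM (log2 fold change -1.76, SE 0.54, edgeR adjusted p = 0.0144). That call was lost without control replicate 1 (edgeR adjusted p = 0.136) and without control replicate 2 (0.150), with log2 fold changes of -1.80 and -1.77. YTHDC1, a nuclear reader of N6-methyladenosine (ENSG00000083896, chromosome 4, 68310387 to 68350089, minus strand), had 48 and 175 counts in the controls and 60 and 249 in EV. Its levels, 5.35 ± 4.27 and 8.08 ± 6.76 CPM, did not differ beyond the replicate spread (log2 fold change 0.60, SE 0.58, edgeR adjusted p = 0.386). With a replicate block, a pairing that the labels do not state, the log2 fold change was 0.575 (edgeR adjusted p = 0.0226). Single samples decided the value without a block. It was 1.76 without control replicate 2 (edgeR adjusted p = 4.33e-06) and -0.71 without EV replicate 2 (0.369).

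The largest rises were ranked by fitted fold change, which is no bound for genes at 0 in both controls. Apart from FRG2B and EFNA2, the bounds of such genes lie below the 251-fold rise of FOS. Among the 10 named, ID2, an inhibitor of basic helix-loop-helix transcription factors, went from 0.722 ± 0.143 to 1106 ± 4.01 CPM (log2 fold change 10.57, SE 0.07, edgeR adjusted p = 8.23e-15). SNAI1, a repressor of epithelial genes, went from 1.11 ± 0.262 to 1114 ± 41.2 CPM (9.97, SE 0.08, edgeR adjusted p = 1.37e-14). EFNA2, an ephrin ligand, had 0 counts in both controls and 65.8 ± 0.0387 CPM in EV, at least 456-fold higher. FRG2B had 0 counts in both controls and 144 ± 0.262 CPM in EV, at least 1000-fold higher, and FRG2EP was at least 214-fold higher. FRG2C rose by a ratio of 1170 (95% interval 323 to 9650). FRG2 copies are near-identical, so the split of reads among them is uncertain, and the same holds for SNORD3B-1, at least 57.3-fold higher. C22orf42, SLC34A2 and ANKRD26P1 were at least 66.5-fold, 64.9-fold and 62.2-fold higher. The 10 largest falls, taken from genes that had a symbol or were protein coding, held 7 noncoding genes. MIR503HG fell by 5.15 on the log2 scale (SE 0.34), KLC1-AS1 by a log2 fold change of -4.64, MIR3142HG of -4.31, ANKRD10-IT1 of -4.29, ALDH1A3-AS1 of -4.14, LINC00342 of -3.94 and NFATC2IP-AS1 of -3.92. Antisense and overlapping genes among these are uncertain without the strand setting. ABCA1, a cholesterol efflux transporter, fell from 86.6 ± 2.15 to 6.04 ± 1.24 CPM (-3.83, SE 0.11, edgeR adjusted p = 2.68e-10). ETAA1, an activator of the ATR kinase, fell from 29.5 ± 0.412 to 2.13 ± 0.0940 CPM (-3.79, SE 0.15). EGLN2, an oxygen-sensing prolyl hydroxylase that overlaps 2 genes on its strand, fell by a log2 fold change of -3.76 (SE 0.33).

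**Figure D2:**
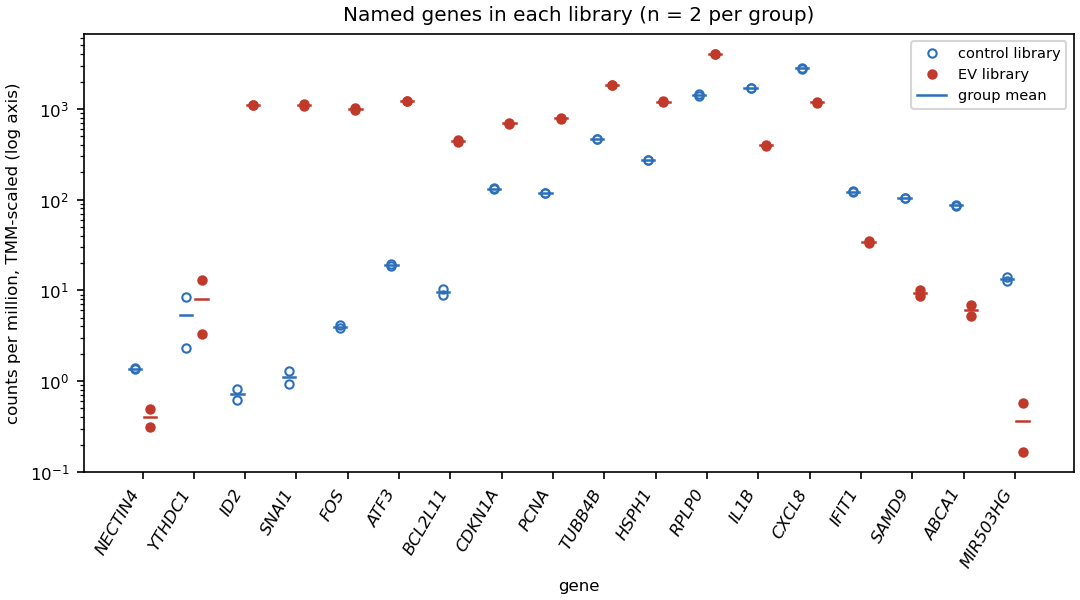
CPM with TMM scaling (log axis) of named genes in each control library (open) and each EV library (filled), n = 2 per group; short lines are group means. FOS lies near 3.99 CPM in the controls and 1002 in EV, IL1B at 1702 and 395, and the YTHDC1 replicates differ within both groups.

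Of 24 AP-1 and immediate early genes tested, 17 rose, 4 fell and 3 did not pass the test (the same adjusted over the list alone). ATF3, a stress-induced transcription factor, rose from 19.1 ± 0.575 to 1226 ± 1.43 CPM, a 64.0-fold rise, and FOSB by a log2 fold change of 4.38. The list was called by camera (adjusted p = 0.00159), but not with an estimated correlation (adjusted p = 0.483). All 13 heat shock genes tested rose, also adjusted over the list alone. The cochaperone DNAJA1 rose by 2.26, HSPH1 by 2.13 and HSP90AB1 by 1.62 in log2 fold change (camera adjusted p = 0.000169; adjusted p = 0.40 with an estimated correlation). Of 19 tubulin and tubulin-folding genes, 12 rose, 3 fell and 4 did not pass, the same adjusted over the list alone. TUBB4B rose from 465 ± 2.52 to 1840 ± 19.4 CPM, TUBA1C by a log2 fold change of 1.61 and TUBB2A by 2.32, whereas TUBB6 fell by 0.44. The camera adjusted p was 0.0367 (adjusted p = 0.40 with an estimated correlation). The call was lost without control replicate 1 (camera adjusted p = 0.0723), without control replicate 2 (0.0681), without EV replicate 1 (0.0752) and after the length and GC correction (0.136).

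Ribosomal protein genes rose almost as a block. Of 50 tested, 48 rose, 1 fell and 1 did not pass, with a median log2 fold change of 1.13 and the same counts adjusted over the list alone. RPLP0 rose by 1.51 and RPLP1 by 1.60 in log2 fold change, and RPS2 from 1272 ± 34.0 to 3588 ± 38.0 CPM (camera adjusted p = 3.95e-13; adjusted p = 0.40 with an estimated correlation). The count of lower members was 0 with DESeq2, with the filter of 50 counts, and without control replicate 1, EV replicate 1 or EV replicate 2. Of 39 nuclear genes of oxidative phosphorylation, 31 rose, 4 fell and 4 did not pass, the same adjusted over the list alone. ATP5F1B, a subunit of ATP synthase, rose by 1.00, NDUFB10 of complex I by 1.08 and COX4I1 of complex IV by 0.84 (camera adjusted p = 0.000151; adjusted p = 0.40 with an estimated correlation). Of 36 replication-dependent histone genes listed, 16 lay below the filter. Of the 20 tested, 15 rose, 1 fell and 4 did not pass, with 16 and 1 adjusted over the list alone. H4C3, with 2 and 1 counts in the controls, passed the filter through its EV counts and could only rise, as could any member so near 0. Its ratio was 304 (95% interval 104 to 1480), and H2BC8 rose by a log2 fold change of 3.60 and H2BC12 by 1.42 (camera adjusted p = 0.000428; adjusted p = 0.40 with an estimated correlation). The count of higher histones was 9 without control replicate 2 and 8 with the filter of 50 counts. These lists hold genes of short spliced length, with medians of 3200, 3236 and 911 bases. After the length and GC correction their camera adjusted p were 2.69e-12, 0.00101 and 0.00511, in the same direction. The correction may leave part of a length effect, because merged exons can be longer than the transcript expressed.

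**Figure D3:**
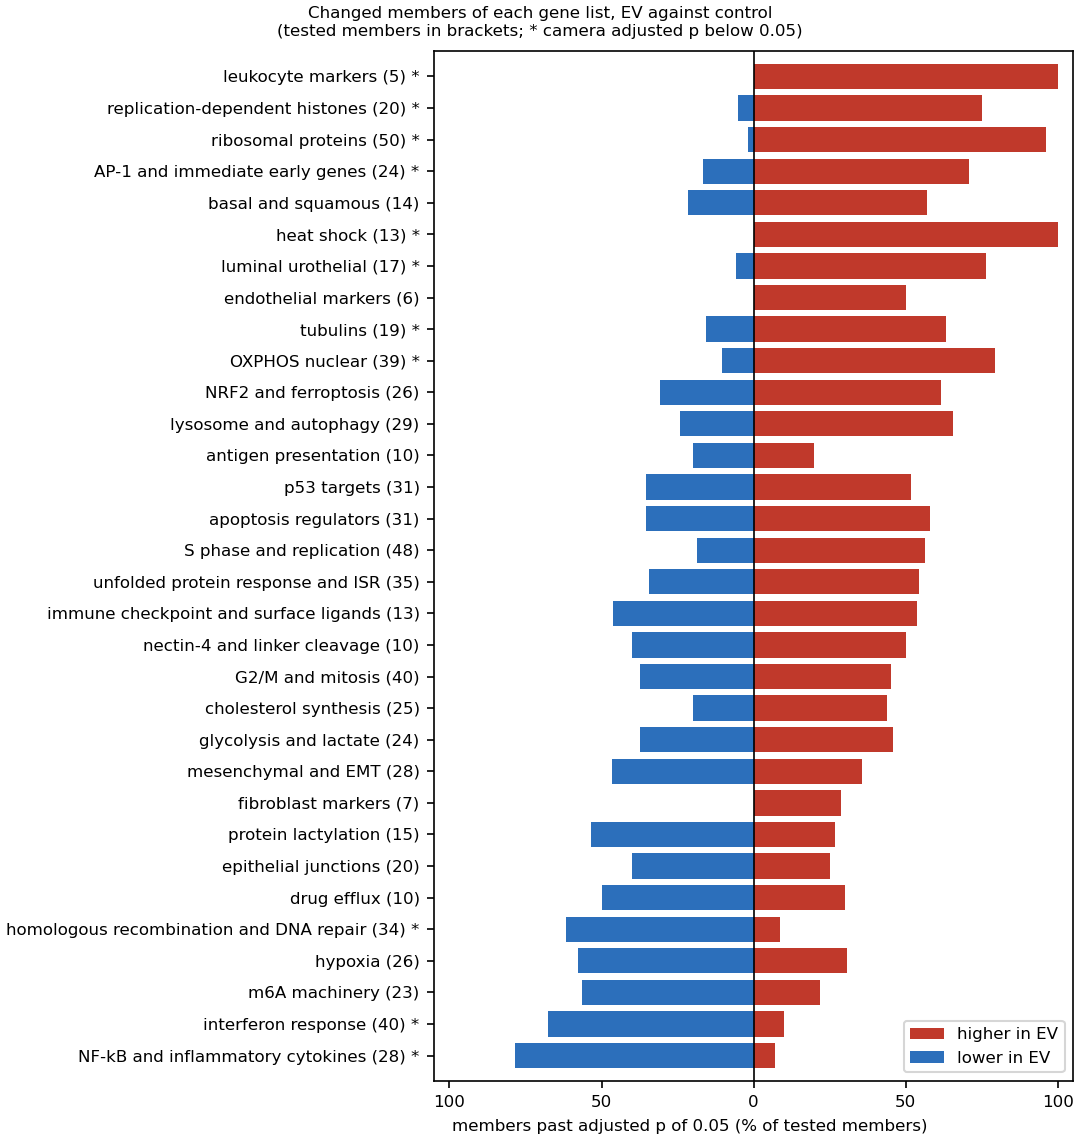
Percent of the tested members of each gene list that were higher (right) or lower (left) in EV than in the controls at an edgeR adjusted p below 0.05; the number tested is in brackets and asterisks mark lists called by camera. All 13 heat shock genes and 48 of 50 ribosomal protein genes rose, and 22 of 28 NF-kB and cytokine genes fell.

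Inflammatory and interferon-response transcripts fell. Of 28 genes of NF-kB signalling and inflammatory cytokines tested, 22 fell, 2 rose and 4 did not pass, the same adjusted over the list alone. Besides IL1B, CSF3, a granulocyte growth factor, fell from 1364 ± 8.10 to 414 ± 6.12 CPM and the chemokine CXCL8 from 2808 ± 41.0 to 1178 ± 28.4 CPM (camera adjusted p = 6.95e-05; adjusted p = 0.40 with an estimated correlation). Of 40 interferon-response genes, 27 fell, 4 rose and 9 did not pass, the same adjusted over the list alone. SAMD9 fell by 3.48 on the log2 scale, IFIT1 fell by 1.82 and OAS3 fell by 1.30 (camera adjusted p = 8e-05; adjusted p = 0.40 with an estimated correlation). Of 34 genes of homologous recombination and DNA repair, 21 fell, 3 rose and 10 did not pass, the same adjusted over the list alone. The kinase ATM fell by 2.05 on the log2 scale, BRCA2 fell by 1.68 and the polymerase POLQ fell by 1.52 (camera adjusted p = 0.0142; adjusted p = 0.40 with an estimated correlation). This list holds genes of long spliced length (median 6357 bases). Its call was lost after the length and GC correction, with 14 lower, 8 higher and a camera adjusted p of 0.136.

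Of 24 luminal urothelial genes listed, 17 could be tested, of which 13 rose, 1 fell and 3 did not pass, the same adjusted over the list alone. Defining markers lay below the filter. KRT20 had 0 counts in all samples, and over controls and EV the uroplakin genes UPK2 and UPK3A had 10 and 14 and 0 and 1 counts. The transcription factor KLF5 rose from 71.7 ± 1.91 to 474 ± 16.4 CPM, keratin KRT8 by a log2 fold change of 1.37 and KRT18 by 0.91 (camera adjusted p = 0.00163; adjusted p = 0.40 with an estimated correlation). The count of lower members was 2 without control replicate 2, without EV replicate 1 and with no count filter, and 0 after the length and GC correction. Of 14 basal and squamous genes, 8 rose and 3 fell, the same adjusted over the list alone, and 3 did not pass. The rises include 5 genes with 0 counts in both controls, which could only rise. KRT5 had 0 counts in both controls and 6.13 CPM in EV, at least 42.4-fold higher, while the receptor EGFR fell by 1.54 on the log2 scale, DSC3 fell by 0.82 and PI3 fell by 1.17. The list was not called (camera adjusted p = 0.121), although it was without EV replicate 1 (0.0292), and 4 members were higher with the filter of 50 counts. Of 28 mesenchymal genes, 10 rose, 13 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.473). Beside SNAI1, the matricellular gene CCN2 rose by 3.39 while its relative CCN1 fell by 1.78 on the log2 scale. Of 20 epithelial junction genes, 5 rose, 8 fell and 7 did not pass, with 7 and 8 adjusted over the list alone (camera adjusted p = 0.652). DSG2 fell by 0.86, CLDN1 fell by 0.75 and JUP fell by 1.02 on the log2 scale. The count of higher junction genes was 3 without control replicate 2 and 1 with the filter of 50 counts. CDH1, the E-cadherin gene, had 1 count over both controls and 16 over both EV samples, below the filter, and KRT19 had 7 and 1.

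Leukocyte, fibroblast and endothelial genes were examined as markers of cell types outside the line. Of 17 genes listed as leukocyte markers, globin genes among them, 5 passed the filter and were higher in EV, also adjusted over the list alone (camera adjusted p = 0.0101, and 0.40 with an estimated correlation). The filter let in genes near 0 in the controls because of their EV counts, and such genes could only rise, so neither the count nor the p is evidence for the list. ITGAM, an integrin subunit of myeloid cells, went from 0.120 ± 0.0351 to 26.0 ± 0.700 CPM. CD79A rose by a ratio of 124 (95% interval 42.2 to 606) and CD14 by a log2 fold change of 2.15. The other 12 genes of this list lay below the filter. Among them were PTPRC with 4 counts over the controls and 13 over EV, LYZ with 0 and 9, and the globin gene HBB with 0 and 4. With the filter of 50 counts 3 markers were higher. Of 7 fibroblast markers, 2 rose (COL6A3 and FAP), 0 fell and 5 did not pass, the same adjusted over the list alone (camera adjusted p = 0.974). The higher count ran from 1 to 5 and the lower from 0 to 2 over the alternatives, with 4 higher and 1 lower without control replicate 1 and 5 and 2 without EV replicate 2; 1 was lower without control replicate 2 or EV replicate 1. Of 6 endothelial markers, 3 rose, 0 fell and 3 did not pass, with 2 higher adjusted over the list alone (camera adjusted p = 0.228). TEK rose by 4.21 and PECAM1 by 1.41 in log2 fold change. TIE1 (0.39, edgeR adjusted p = 0.0484) lost its call without any one of the 4 samples, at edgeR adjusted p of 0.507 and 0.0583 without control replicates 1 and 2, and 0.106 and 0.0768 without EV replicates 1 and 2. It was also lost with DESeq2 (adjusted p = 0.115) and with no count filter (edgeR adjusted p = 0.171).

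Cell cycle and death genes moved both ways, as did all 17465 genes tested, of which 6019 rose and 5509 fell. Of 40 genes of G2/M and mitosis, 18 rose, 15 fell and 7 did not pass (camera adjusted p = 0.719). The kinase NEK2 rose by 1.87, while ASPM fell by 2.24 and CENPF fell by 1.61 on the log2 scale. Of 48 genes of S phase and replication, 27 rose, 9 fell and 12 did not pass (camera adjusted p = 0.0736). The replication clamp PCNA rose from 118 ± 0.353 to 784 ± 4.10 CPM, TK1 by a log2 fold change of 0.98 and E2F1 by 1.04. Of 31 p53 targets, 16 rose, 11 fell and 4 did not pass (camera adjusted p = 0.444). The cyclin-dependent kinase inhibitor CDKN1A rose by 2.40, GADD45A by 2.52 and PLK2 by 1.58. Of 31 apoptosis regulators, 18 rose, 11 fell and 2 did not pass (camera adjusted p = 0.363). Beside BCL2L11, PMAIP1, which encodes the pro-apoptotic protein NOXA, rose by 0.80. Of 35 genes of the unfolded protein and integrated stress responses, 19 rose, 12 fell and 4 did not pass (camera adjusted p = 0.363), with ATF4 higher by 1.17 and CEBPB at -1.40. Adjusted over the list alone, the counts of these 5 lists were the same.

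Lists on the subjects of the series title and on the drug target were not called by camera. Fry, which does not compare a list with other genes, gave adjusted p of 0.0144 for the m6A machinery, 0.0017 for glycolysis and lactate, 0.00513 for protein lactylation and 0.0157 for nectin-4 and linker cleavage. Of 23 genes of the m6A machinery, 5 rose, 13 fell and 5 did not pass (camera adjusted p = 0.148). This list holds genes of long spliced length (median 6641 bases). After the length and GC correction its median log2 fold change went from -0.55 to -0.12, with 5 higher and 11 lower (camera adjusted p = 0.414). IGF2BP1 fell by 1.43 on the log2 scale, and the RNA-binding HNRNPA2B1 and HNRNPC rose by 0.78 and 0.72. Of 24 genes of glycolysis and lactate, 11 rose, 9 fell and 4 did not pass (camera adjusted p = 0.880), with PFKFB3 higher by 2.45, GAPDH by 0.95 and ENO1 by 0.86. Of 15 genes of protein lactylation, 4 rose, 8 fell and 3 did not pass (camera adjusted p = 0.363). AARS1 fell by 0.83 on the log2 scale, and the acyltransferase genes CREBBP and EP300 fell by 0.73 and fell by 0.75. Counts in these 3 lists were the same adjusted over the list alone. Of 10 genes of nectin-4 and linker cleavage, 5 rose, 4 fell and 1 did not pass, with 6 and 4 adjusted over the list alone (camera adjusted p = 0.924). The clathrin heavy chain gene CLTC fell by 0.79 and the protease CTSS fell by 0.89 on the log2 scale, while RAB7A rose by 0.33.

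The other lists were not called by camera either, while fry called each of those below that could be tested except drug efflux (adjusted p = 0.133). Of 26 hypoxia genes, 8 rose, 15 fell and 3 did not pass (camera adjusted p = 0.206), with ADM higher by 2.28, BHLHE40 by 0.98 and VEGFA at -1.90. Of 25 genes of cholesterol synthesis, 11 rose, 5 fell and 9 did not pass (camera adjusted p = 0.321), with IDI1 higher by 2.45 and HMGCS1 by 1.96. Of 26 NRF2 and ferroptosis genes, 16 rose, 8 fell and 2 did not pass (camera adjusted p = 0.122), with TFRC higher by 0.98, SLC3A2 by 0.99 and TXNRD1 at -0.90. Of 29 genes of lysosome and autophagy, 19 rose, 7 fell and 3 did not pass, with 19 and 8 adjusted over the list alone (camera adjusted p = 0.0822). MAP1LC3B rose by 2.18 and ATP6V0D1 by 1.27. Of 10 drug efflux genes, 3 rose, 5 fell and 2 did not pass (camera adjusted p = 0.415), with ABCB1, the P-glycoprotein gene, up from 16.9 ± 1.07 to 77.6 ± 4.68 CPM and ABCC3 and MVP at -0.72 and -0.49. Of 13 immune checkpoint and surface ligands, 7 rose and 6 fell (camera adjusted p = 0.724), with ULBP2 higher by 1.21, PVR by 0.54 and PDCD1LG2 at -1.49. Of 10 antigen presentation genes tested, 2 rose, 2 fell and 6 did not pass (camera adjusted p = 0.719). B2M rose by 0.39, ERAP2 stood at -1.60 and ERAP1 at -0.44, the last not past the threshold after the length and GC correction (-0.04, edgeR adjusted p = 0.604). Apart from the lysosome list, counts in this group were the same adjusted over the list alone. The 13 mitochondrial genome genes had 0 counts and were not tested. List median, mean and test differed in sign for 4 lists: nectin-4 and linker cleavage (0.17, -0.20, down), mesenchymal genes (-0.07, 0.16, down), epithelial junctions (-0.28, 0.50, down) and fibroblast markers (-0.09, 0.72, down).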

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

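The length and GC correction was chosen after the result was seen. The count of changed genes stayed within 1.5 times under each alternative that kept the threshold. It was 11744 with DESeq2 (6432 higher, 5312 lower), 11507 with RLE and 11477 with upper quartile scaling, 12276 with no count filter, 9409 with the filter of 50 counts and 11080 after the length and GC correction. Leaving out 1 sample gave 9538 to 11772 changed genes, with 4926 to 5983 higher and 4611 to 5789 lower, the lone sample being assumed to vary like the other group. A minimum absolute log2 fold change of 1 left 5385 genes, 3063 higher and 2322 lower, by construction. Another scaling moved the median of all genes by at most 0.06 in log2. Each of these scalings centres the bulk of genes, so a shift common to all genes would go unseen. Of the 11 lists called by camera, 0 were called with an estimated correlation (smallest adjusted p = 0.40), and fry, which does not compare a list with other genes, called 30. Camera with an estimated correlation has little power with 2 samples per group. Leaving out 1 sample gave 10 to 11 lists. The correction kept 9 of the 11 in the same direction. Of list members, 7 reversed with both values past the threshold: ALKBH5 (-0.12), PDK1 (0.30), BCL2L1 (-0.11), FOSL1 (-0.38), SDHC (0.39), CALD1 (0.17) and CD47 (0.15) after the length and GC correction, beyond which the cause was not tested. Over all genes the replicate numbers showed no pairing of the samples: replicate differences correlated between groups at r = 0.016. A replicate block gave 11530 changed genes (5957 higher, 5573 lower) and 11 lists, and YTHDC1 then had an edgeR adjusted p of 0.0226. Depth limits genes near the floor, such as NECTIN4 with 6 to 29 counts.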

Other observations

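Genes and lists outside the fixed lists were chosen after their values were seen, and so were both YTHDC1 tests, the tubulin test, the length and GC correction and the MHC comparison. HEXIM1, an inhibitor of the elongation kinase P-TEFb, rose from 103 ± 0.933 to 763 ± 43.6 CPM, and SERTAD1 by a log2 fold change of 2.98. The reductase gene DHRS2 rose from 3.77 ± 0.476 to 164 ± 6.13 CPM. RGS16, a regulator of G protein signalling, went from 0.120 ± 0.0351 to 57.6 ± 0.202 CPM. The secreted chaperone CLU rose by 2.46. Growth factor genes INHBA and PDGFB fell by 2.98 and fell by 2.93 on the log2 scale, and the histone methyltransferase gene KMT2A fell by 2.94, all at an edgeR adjusted p below 0.05.

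A list of 24 genes known from cleavage-stage embryos and DUX4 activity, chosen after FRG2B was seen, had 18 members with 0 counts in both controls. The 7 members that passed the filter were higher, but among them CCNA1 alone had more than 1 count over both controls, so the others could only rise and their shared direction is no evidence for the list. ZSCAN4 had 0 counts in both controls and 30 and 38 in EV, at least 12.5-fold higher, and TRIM43 had 84 and 54, at least 25.7-fold higher. CCNA1 rose from 5.24 ± 0.293 to 35.7 ± 0.612 CPM. DUXA had 0 counts in all 4 samples and LEUTX had 5 and 8 in EV. By annotated type, 59 of 121 sense intronic transcripts fell and 14 rose, where 5509 of all 17465 genes tested fell and 6019 rose.

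Of 39357 genes with at most 3 counts over both controls, 183 reached 2 CPM or more in EV, 108 of them protein coding. If the EV libraries came from another cell line, genes should be lost as well as gained, but the reverse set held 8 genes, 4.4% of the gained number. A uniform rate of genomic DNA would bring 9.37 genes to that level, far fewer than 183. That value covers an even rate per kb only, and genomic DNA spread unevenly over genes was not examined. Read-through of up to 10 kb from the nearest same-strand gene upstream is argued against for most of them. Of 178 with annotation, 29 (16.3%) began within 10 kb downstream of such a gene that was expressed. Longer read-through, or that from an overlapping gene, was not examined. The share of 16.3% was above the 2.5% of genes that stayed silent (Fisher's exact p = 1.75e-15), so read-through may account for those 29. Longer read-through, unevenly spread genomic DNA, a response to EV and RNA from an untested source remain open for the rest.

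Genes of long spliced length were lower and those of short spliced length higher in EV. In the decile of longest spliced length 75.7% fell, and in that of the shortest 68.7% rose. At fixed gene span and GC content the correlation of fold change with spliced length was -0.298 across genes (95% bootstrap interval -0.318 to -0.277), which is consistent with an effect of RNA quality or library preparation. The correlation with gene span at fixed spliced length was -0.086 (-0.108 to -0.064), an interval that crosses the bound of -0.1 set for it, so a biological effect on long transcription units cannot be told apart. After the trend was removed, 9 of 11 called lists kept their direction and side of the threshold. Without the leukocyte markers, which carry no weight, 8 of 10 did. The histone list, among those 8, counts for less, because H4C3 and any member so near 0 in the controls could only rise. That most called lists were kept argues against the trend with merged exon length as the whole cause of the list calls. This argues against the trend with merged exon length as the whole cause of the list calls. The correction does not exclude an effect of the length of the transcripts expressed, which was not measured. For tubulins the median went from 0.58 to 0.39 and the members from 12 higher and 3 lower to 10 and 5, and for DNA repair the median went from -0.41 to -0.19, smaller effects that ended both calls.

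YTHDC1 counts differed 3.6-fold between the control replicates and 3.9-fold between the EV replicates, replicate 2 being higher in both. Sampling noise of independent reads is argued against by exact binomial tests (p = 7.03e-18 in the controls and 4.06e-26 in EV), which cover counting error only and leave duplicated reads open. A batch shared by samples of the same number and acting on most genes is argued against by the correlation of 0.016 between the groups' replicate differences across all genes. That value includes genes of low count and cannot exclude a factor tied to the replicate number that acts on YTHDC1 or few genes. Among 10900 genes with 400 or more counts in total no other gene differed by at least 1.5 in log2 the same way in both groups, but these bounds were set after YTHDC1 was seen, so its own place beyond them is no evidence. No biological explanation was tested, and a difference in how reads of this gene were counted remains open.

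One hypothesis was that loss of microtubules lowers tubulin transcripts through tubulin autoregulation, in which free tubulin triggers decay of its own messages through TTC5. Of 11 alpha and beta tubulin genes tested, 8 rose, 2 fell and 1 did not pass, which is not the fall that this hypothesis predicted. Free tubulin was not measured, so the counts do not decide whether autoregulation acted. TUBB, with 2 to 6 counts per sample, could not be tested. Over the alternatives 6 to 8 rose and 2 to 3 fell. TTC5 itself fell by 0.88 on the log2 scale.

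In the MHC region, TUBB had 2 to 6 counts per sample and HLA-C had 0, with 2 of 153 protein coding genes at 10 or more counts in every sample against 511 of 886 elsewhere on chromosome 6 (Fisher's exact p = 6.48e-47).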
